A study of Mus musculus with 12 samples.

How the data were processed

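RNA was measured on Illumina mouse bead arrays in mouse embryonic fibroblasts (MEFs) of 2 genotypes, TAp73+/+ and TAp73-/-. TAp73 is the isoform class of the transcription factor p73, encoded by Trp73, that carries the transactivation domain. Per the labels, cells of each genotype were left untreated or kept at 1% oxygen for 4 or 8 h, RNA was extracted with Trizol and a column kit, and biotinylated cRNA was hybridised. There are 2 arrays in each of 6 groups and 12 in all. The labels do not say whether the 2 replicates of a group are separate cultures, so the tests measure the spread between arrays, whatever that contains. They name no slide or date either, so no slide block was run. Each genotype may be represented by a single MEF line, and genotype and line are then the same contrast.

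The deposited non-normalised table holds, per the file headers, an intensity signal and a detection p-value for each of 45281 probes on each array. The deposited series matrix holds 1 processed intensity signal per probe and array on a linear scale, which the submitters' processing notes attribute to Partek without a version. Its values have the same rank order as the signals of the same array (rank correlation 1) and one distribution on all arrays, with a median of 71.5. It therefore holds quantile-normalised signals and was used as an alternative only. The lowest step of the detection p-value was 0.00107.

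The signals were background-corrected by normexp with the background estimated from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalised and put on the log2 scale (neqc of limma 3.58.1 in R 4.3.3). A probe was kept if its detection p-value was below 0.05 on both arrays of at least 1 group, which left 21223 probes. Probes were named from the platform annotation, in which 34885 probes have 1 gene symbol, 18 have several and 10378 have none. Symbols were updated through the Entrez identifier in a table of the GRCm38.p6 assembly, which matched 34807 probes. Of the probes kept, 17891 have 1 symbol and 3332 have no single symbol and were left out of the tests by gene. Each gene is represented by its probe with the highest mean signal, which gave 10873 genes, of which 4571 have more than 1 probe past the filter. Where another probe past the filter had the opposite sign, this is given for some called genes, but not beside every value. Genes whose copies are nearly identical, such as the replication-dependent histones, may share signal between probes.

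Detection was reached by 19362 to 20133 probes per array, 42.8% to 44.5% of all. The number of arrays limits the precision of every comparison.

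A model with 1 mean per group was fitted to all 12 arrays with limma, with empirical Bayes moderation (residual degrees of freedom 6, prior 4.79, total 10.8), and 10 contrasts were tested. These are hypoxia against untreated at 4 and 8 h in each genotype, TAp73-/- against TAp73+/+ untreated, at 4 h, at 8 h and averaged over the 3 times, and the difference between the genotypes in the 4 h and in the 8 h response. Standard errors are those of the moderated model. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. Positive values mean higher at hypoxia, higher in TAp73-/-, or, for the difference in response, a response that is more positive in TAp73-/-.

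A fold against a group in which the gene was not detected on either array is given as at least N-fold, measured against the lowest signal among detected probes of each array of that group or the probe's own signal, whichever was higher. All other changes are log2 differences of normalised values.

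The genes in the text follow a rule set before the data were examined. It names Trp73, Trp63, Trp53, Hif1a, Epas1, Arnt and Vegfa. For each contrast it adds up to 8 called genes with the largest rises and 8 with the largest falls among those whose arrays do not overlap between the groups. For each list it adds the called members with the largest changes, up to 4 each way, or where none was called up to 2 with the largest change. It also takes genes called for a difference in response and the sex-linked genes. The contrasts, the lists, the threshold and the other alternatives described here were also chosen before the data were examined, apart from those said to be later. The genes in the plots of the hypoxia and interferon genes, the histone set, the markers of cell identity and the flanking genes were chosen later.

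The 22 lists cover glycolysis and glucose uptake, canonical hypoxia-inducible genes, angiogenic factors and regulators, p53-family target genes, S phase and mitosis, oxidative phosphorylation subunits, sterol synthesis, the unfolded protein and amino acid stress response, extracellular matrix and contractile genes, inflammatory cytokines and NF-kappaB targets, interferon-stimulated genes, immediate early genes, Hox positional genes, sex-linked genes, housekeeping genes, and markers of endothelial, epithelial, macrophage and blood, skeletal muscle, adipocyte, cartilage and bone, and neural cells. The 17 lists with at least 5 measured genes were tested against all other genes with camera in limma, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. The second is quoted where it ends a call. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of 1 list only.

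The procedure was tested on simulated data for the 8 h contrast in TAp73+/+, with 10873 genes and 50 genes changed at each of 4 sizes. It called 21 of 50 genes changed by 0.5 on the log2 scale, 46 of 50 changed by 1, 50 of 50 changed by 1.5 and 50 of 50 changed by 2, with 7 calls among unchanged genes. With no gene changed, 0 were called. The simulated noise was independent between genes, so these counts leave out any difference between arrays that many genes share.

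A score for the disagreement between probes of 1 gene was added after the data had been examined. It is the first principal component of the differences between probe and gene mean over 5474 probes of 2353 genes with a mean log2 signal above 7, which carried 56.0% of the variance, against 21.1% for the second.

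The alternatives were no background correction, median scaling in place of quantile normalisation, the deposited processed values, no filter on dim probes, a detection p-value below 0.01, an intensity trend in the moderation, the replicate number as a block, only the arrays of the compared groups, every probe counted, an added threshold of 1 on the log2 change, each array left out in turn, and the estimated correlation for the lists. The probe score as a covariate and the correlation of the responses without each array were added later. Trp53 is not analysed here, and neither are probes without a gene symbol.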

Results

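Transcript levels were measured on 12 Illumina mouse bead arrays, 2 for each combination of genotype (TAp73+/+ or TAp73-/- MEFs) and condition (untreated, or 4 or 8 h at 1% oxygen). The mean probe signal was 557 and 608 on the arrays of untreated TAp73+/+ cells, 578 and 563 at 4 h and 533 and 507 at 8 h. It was 555 and 501 on those of untreated TAp73-/- cells, 487 and 537 at 4 h and 441 and 429 at 8 h. Between 42.8% and 44.5% of the 45281 probes were detected on each array. Arrays of the same group correlated across probes at r = 0.993 to 0.997, and the median absolute difference between them was 0.0869 to 0.168 on the log2 scale. The first principal component carried 58.4% of the variance between arrays and the second 17.8%. All comparisons below use 2 arrays per group, and adjusted p-values are from limma.

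Trp73 was read by 1 probe. It was not detected on any of the 6 TAp73+/+ arrays, with group means of 4.76, 4.48 and 4.64 (log2 signal, n = 2 each) untreated, at 4 h and at 8 h. On arrays labelled TAp73-/- it was detected on 1 of 2 untreated arrays and on both arrays at each time of hypoxia, with means of 5.02, 5.86 and 6.22. It was at least 1.73-fold higher in TAp73-/- at 4 h (adjusted p = 0.000774) and at least 2.25-fold higher at 8 h (adjusted p = 0.000294). Untreated, the difference of 0.26 ± 0.22 (SE) was not called (adjusted p = 0.372). Within TAp73-/- the signal rose by 0.85 ± 0.22 at 4 h (adjusted p = 0.0436) and by 1.21 ± 0.22 at 8 h (adjusted p = 0.00355). The rise at 4 h within TAp73-/- was 0.91 ± 0.35 with the probe score as a covariate and no longer called (adjusted p = 0.343), while the difference between genotypes at 4 h stayed called (adjusted p = 0.00949). Averaged over the 3 times the genotypes differed by 1.08 ± 0.13 (adjusted p = 3.19e-05). With the covariate this was 1.16 ± 0.40, as large but no longer called because the SE grew (adjusted p = 0.0946). Whether the response differed between genotypes was not settled, with differences of 1.13 ± 0.31 at 4 h (adjusted p = 0.11) and 1.33 ± 0.31 at 8 h (adjusted p = 0.0859). Whether the probe lies inside the deleted part is not known here, so Trp73 does not check the genotype labels. Probes for Trp63 and Epas1 were below detection on all arrays.

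The comparisons of hypoxia with untreated cells ask which transcripts low oxygen changes in MEFs labelled TAp73+/+. At 4 h the genes that mark a response to low oxygen rose together in TAp73+/+. Adm, which encodes the vasodilator peptide adrenomedullin, rose by 2.74 ± 0.18 (log2, SE; adjusted p = 4.68e-06), Stc1 by 2.59 ± 0.11 (adjusted p = 4.41e-07) and the growth factor gene Vegfa by 1.74 ± 0.09 (adjusted p = 1.02e-06). Egln1, the oxygen sensor that marks HIF for degradation, rose by 2.73, the lipoprotein receptor Vldlr by 2.55, the glucose transporter Slc2a3 by 1.77, the lactate exporter Slc16a3 by 1.77 and Pdk1, which diverts pyruvate from mitochondria, by 1.72. Smtnl2 was at least 4.09-fold higher. Clustered histone genes fell, with changes of -2.45 for H2ac21, -2.43 ± 0.11 for H1f2 (adjusted p = 5.22e-07) and -2.24 for H2ac11. Txnip, an inhibitor of glucose uptake, fell by 1.76.

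Of the 33 canonical hypoxia-inducible genes, 24 were higher at 4 h, 1 was lower and 8 were not called, or 25 higher and 1 lower adjusted over the list alone (median 1.23, camera adjusted p = 3.84e-21). Of the 19 glycolysis and glucose uptake genes, 13 were higher and 1 lower, Pfkfb4 at -0.46 (15 and 1 adjusted over the list alone, median 0.58, adjusted p = 2.09e-10). The unfolded protein and amino acid stress response had 14 of 25 genes higher and none lower (15 adjusted over the list alone, median 0.39, adjusted p = 1.88e-07). Its rises included Trib3 at 2.28 and Chac1 at 1.54, both targets of the transcription factor ATF4. Immediate early genes had 11 of 18 higher and 2 lower (12 and 4 adjusted over the list alone, median 0.45, adjusted p = 0.00133), with Ier3 at 2.12 and Dusp1 at 1.11 rising and Ier2 at -1.07. That list's call ended at adjusted p = 0.116 with an estimated correlation. Tnfrsf10b, a death receptor gene of the p53-family targets, rose by 1.34, and Ddit4 by 1.23.

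Lists without a call at 4 h in TAp73+/+ moved in both directions. Interferon-stimulated genes had 2 of 25 higher and 6 lower (median -0.18, adjusted p = 0.436), with Usp18 at -0.80 (0.21 by its other probe) and Parp14 at -0.77. Hox positional genes had 7 of 22 lower and none higher (median -0.17, adjusted p = 0.0674), and sterol synthesis genes 6 of 17 lower and 1 higher (median -0.27, adjusted p = 0.103), including Insig1 at -0.88, where 2 of 3 probes were lower, and Stard4 at -0.72. The S phase and mitosis list had 6 of 31 higher, such as Mcm3 at 1.32 and Ccne2 at 1.29, and 4 lower, such as Aurka at -0.66 and Plk1 at -0.65 (adjusted p = 0.922). Angiogenic factors split 6 to 4 of 29 (adjusted p = 0.279), p53-family targets 7 to 2 of 25 (adjusted p = 0.0689), inflammatory genes 3 to 3 of 17 and extracellular matrix genes 2 to 0 of 15, with adjusted p = 0.436 for each of these last lists. Oxidative phosphorylation subunits had 5 of 35 higher and none lower (1 adjusted over the list alone, median 0.08, adjusted p = 0.103), and with the covariate the list was called lower (median -0.27, adjusted p = 0.00976). Hif1a itself read 1.59 higher, and its other probe past the filter also rose, from 4.45 to 6.09. With the probe score as a covariate its sign turned to -0.12. In TAp73-/- Hif1a changed by 0.49 at 4 h (not called, adjusted p = 0.223) and by -0.514 at 8 h. The probes disagreed there at 8 h, since the other one rose from 4.385 to 5.61.

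By 8 h in TAp73+/+ the same families were called. Adm reached 3.27 ± 0.18 (adjusted p = 7.22e-07), Stc1 2.99 ± 0.11 (adjusted p = 1.09e-07), Slc16a3 2.80, the stress gene Ndrg1 2.53 ± 0.11 (adjusted p = 1.81e-07), Pdk1 2.33, the keratin gene Krt19 2.18 and Vegfa 1.79 ± 0.09 (adjusted p = 3.48e-07). Smtnl2 was at least 5.55-fold higher and the VEGF relative Pgf at least 2.48-fold. The linker histone gene H1f2 fell by 4.13 ± 0.11 (adjusted p = 9.13e-09), and other histone genes fell too, such as H2ac21 at -3.35, H2ac11 at -3.21 and H2bc4 at -2.49. The mitotic genes Cdc20 at -1.11 (lower by 3 of 4 probes), Plk1 at -1.01 and Nusap1 at -0.79 were lower, while E2f1 was higher at 0.83.

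Of the canonical hypoxia-inducible genes 26 were higher and none lower at 8 h (27 and 1 adjusted over the list alone, median 1.49, adjusted p = 2.24e-23), and of the glycolysis genes 17 and none (18 adjusted over the list alone, median 0.93, adjusted p = 2.52e-17). Stress response genes had 13 higher and 1 lower (15 and 2 adjusted over the list alone, median 0.35, adjusted p = 1.29e-06), with Trib3 at 1.98 and Ddit3 at 1.35. Immediate early genes had 11 higher and 1 lower (13 and 3 adjusted over the list alone, median 0.57, adjusted p = 2.09e-06), with Atf3 at 2.03, Dusp1 at 1.79 and Fosb at 1.76. Inflammatory cytokines and NF-kappaB targets had 9 of 17 higher and 1 lower, and the same adjusted over the list alone (median 0.52, adjusted p = 3.66e-05). Cxcl2 rose by 1.67, Tnfaip3 by 1.63, Cxcl1 by 1.25 and Nfkbia by 0.96.

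Further lists were called at 8 h in TAp73+/+ with the preset correlation only. Angiogenic factors had 9 higher and 1 lower (median 0.24, adjusted p = 0.0045, and adjusted p = 0.0565 with an estimated correlation). P53-family targets had 6 higher and 1 lower (median 0.16, adjusted p = 0.0172, and adjusted p = 0.0565 with an estimated correlation), with Gadd45a at 0.89. Extracellular matrix genes had 3 higher and none lower, Fn1 among them at 1.04 (adjusted p = 0.035, and adjusted p = 0.0913 with an estimated correlation). Sterol synthesis genes had 5 lower and none higher (8 lower adjusted over the list alone, median -0.31, adjusted p = 0.00726, and adjusted p = 0.0565 with an estimated correlation), with Idi1 at -0.59 and Tmem97 at -0.51. Interferon-stimulated genes had 8 lower and 1 higher (median -0.20, adjusted p = 0.0306, and adjusted p = 0.111 with an estimated correlation), with Usp18 at -1.20, Gbp2 at -1.18 (0.064 by its other probe) and Ifih1 at -0.94. The member called higher was the chemokine gene Cxcl10 at 1.42. Hox genes had 5 lower and 1 higher (median -0.25, adjusted p = 0.0415, and adjusted p = 0.0929 with an estimated correlation), with Hoxa7 at -0.76. S phase and mitosis genes split 8 to 7 (adjusted p = 0.778), and oxidative phosphorylation subunits had 3 lower (adjusted p = 0.856), called lower with the covariate (median -0.15, adjusted p = 0.0114).

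In total 3043 of 10873 genes were called at 4 h in TAp73+/+ (1304 higher and 1739 lower) and 2599 at 8 h (1262 and 1337). Of these, 253 and 103 at 4 h and 159 and 78 at 8 h also differed by at least 1 on the log2 scale. Samples differed in how the probes of 1 gene disagree. The score of that disagreement is signed and gives a position along 1 pattern, not an amount. It was 0.640 and 0.384 on the untreated TAp73+/+ arrays against -0.139 and -0.154 at 4 h and 0.137 and 0.269 at 8 h. Where a called gene had a second probe, 71.4% of second probes had the same sign at 4 h and 80.6% at 8 h. With the score as a covariate the median SE rose from 0.127 to 0.354 at 4 h and to 0.196 at 8 h, since the score nearly follows the untreated group, and 20 and 679 genes were called, 20 and 581 of them also called without it. The hypoxia-inducible list then had a median of 1.12 with 6 genes called at 4 h and of 1.38 with 22 called at 8 h. Among single genes at 4 h, Vegfa (1.98, adjusted p = 0.0234) and Stc1 (adjusted p = 0.0194) stayed called, while Phgdh moved from 2.68 to 0.93, Rbbp7 (3 of 4 probes higher) from 2.51 to 0.27, Hnrnpk from 2.41 to 0.39, Tnfrsf10b from 1.34 to 0.76 and Pfkfb4 from -0.46 to -0.028, and Mcm3, Ccne2 and Insig1 turned sign to -0.092, -0.64 and 0.30. Of the 94 called genes named by the rule at 4 h, 70 lost the call and 13 turned sign, and of 86 at 8 h 39 lost it and 1 turned sign. At 8 h Fn1 moved from 1.04 to 0.67, Gadd45a from 0.89 to 0.49 and Idi1 from -0.59 to -0.37, and each lost its call. Without the first array at 4 h 1496 genes were called there, without the second 1478 and without the first untreated array 1823. At 8 h 1212 were called without the first array of that time and 1370 without the second.

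**Figure D1:**
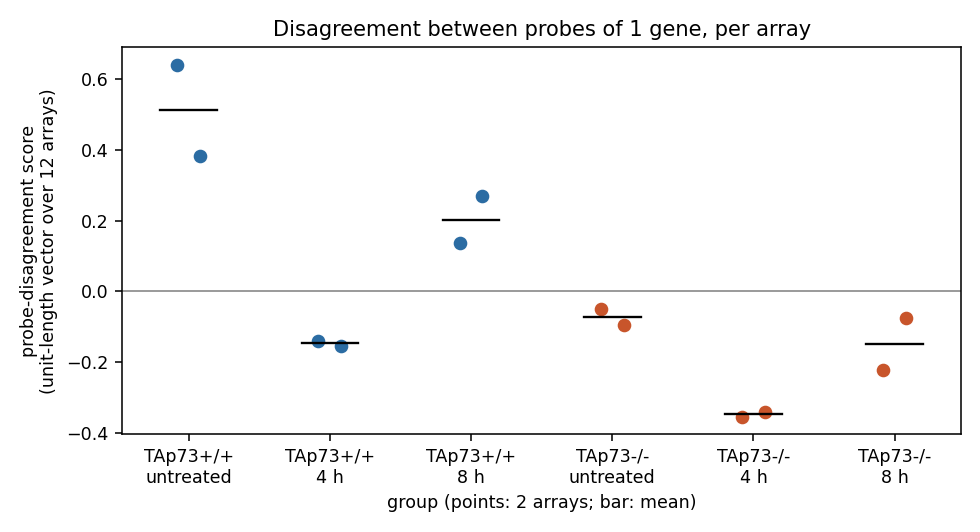
The score for disagreement between probes of 1 gene (vertical axis, a unit-length vector over 12 arrays, no unit) is plotted for the 2 arrays of each group (points) with the group mean (bar). Untreated TAp73+/+ arrays lie at 0.640 and 0.384, and those of TAp73-/- at 4 h at -0.354 and -0.341. The sign gives the direction of the disagreement, so a lower value is not less disagreement.

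The same comparison in TAp73-/- asks which of these changes occur in cells labelled as lacking TAp73. At 4 h Adm rose by 2.88 ± 0.18 (adjusted p = 6.11e-06), the hormone gene Stc2 by 2.30, the lipid droplet gene Hilpda by 2.10 ± 0.09 (adjusted p = 7.34e-07), Ndrg1 by 2.09 ± 0.11 (adjusted p = 2.88e-06), Stc1 by 2.03, Vegfa by 1.57 ± 0.09 (adjusted p = 3.06e-06) and the glucose transporter Slc2a1 by 1.55. Smtnl2 was at least 4.16-fold higher. Txnip fell by 2.996 ± 0.13 (adjusted p = 7.34e-07). Among histone genes H2ac21 was lower at -1.68, H1f2 at -1.62 and H2ac11 at -1.60. Interferon-stimulated genes fell, with Igtp at -1.17, Gbp2 at -1.13, Ifit3 at -1.03 and Dhx58 at -0.86.

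Of the hypoxia-inducible genes 25 were higher and none lower at 4 h (28 adjusted over the list alone, median 1.08, adjusted p = 5.79e-37), and of the glycolysis genes 9 and none (12 adjusted over the list alone, median 0.42, adjusted p = 2.28e-11). Interferon-stimulated genes had 10 of 25 lower and none higher (15 adjusted over the list alone, median -0.48, adjusted p = 1.49e-09). A further 5 lists, skeletal muscle markers among them, were called with the preset correlation only. Stress response genes had 4 higher (median 0.08, adjusted p = 0.0305, and adjusted p = 0.144 with an estimated correlation), immediate early genes 3 higher and 1 lower (adjusted p = 0.0329, and adjusted p = 0.188 with an estimated correlation), and Hox genes 1 lower (adjusted p = 0.0305, and adjusted p = 0.13 with an estimated correlation). Oxidative phosphorylation subunits had no gene called (median 0.11, adjusted p = 0.0413, and adjusted p = 0.556 with an estimated correlation). Not called as lists were inflammatory genes (1 higher, 1 lower, adjusted p = 0.95), angiogenic factors (4 and 3, adjusted p = 0.201), p53-family targets (3 and 0, adjusted p = 0.0696), extracellular matrix genes (2 and 1, adjusted p = 0.685), sterol synthesis genes (0 and 1, adjusted p = 0.483) and S phase and mitosis genes (1 and 1, adjusted p = 0.948).

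At 8 h in TAp73-/- Adm was higher by 2.79 ± 0.18 (adjusted p = 3.91e-06), Ndrg1 by 2.40, Stc1 by 2.37, Hilpda by 2.30 ± 0.09 (adjusted p = 1.55e-07), the stress gene Ddit3 by 1.95, Slc2a3 by 1.90 and Vegfa by 1.42 ± 0.09 (adjusted p = 3.34e-06). Smtnl2 was at least 7.25-fold higher and Pgf at least 3.44-fold. H1f2 fell by 3.37 ± 0.11 (adjusted p = 8.08e-08), and the mitochondrial transcript ND4L was at -2.90 and H2ac21 at -2.21. The interferon-induced GTPase gene Ifi47 fell by 1.67, with Gbp2 at -1.42 and Oas1a at -1.28. P53-family targets rose in part, Gadd45a by 1.08, Bbc3 by 0.76 and Fas by 0.71, while Aen fell by 0.78.

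Hypoxia-inducible genes had 27 of 33 higher and none lower at 8 h (28 and 1 adjusted over the list alone, median 1.24, adjusted p = 2.31e-22), and glycolysis genes 17 of 19 (all 19 adjusted over the list alone, median 0.60, adjusted p = 1.88e-14). Stress response genes had 12 higher (13 adjusted over the list alone, median 0.40, adjusted p = 4.52e-06), p53-family targets 11 higher and 1 lower (12 and 2 adjusted over the list alone, median 0.33, adjusted p = 0.000459), and inflammatory genes 6 higher (9 adjusted over the list alone, median 0.35, adjusted p = 0.000307). Hox genes had 8 lower and none higher (11 adjusted over the list alone, median -0.33, adjusted p = 0.000459), among them Hoxb3 at -0.71 and Hoxd10 at -0.70. Interferon-stimulated genes had 9 lower and 1 higher (11 and 2 adjusted over the list alone, median -0.24, adjusted p = 0.000302). Immediate early genes had 7 higher and 3 lower (adjusted p = 0.00587, and adjusted p = 0.112 with an estimated correlation). Not called were angiogenic factors (6 higher, 3 lower, adjusted p = 0.0893), sterol synthesis genes (4 lower, adjusted p = 0.0893), S phase and mitosis genes (2 higher, 6 lower, adjusted p = 0.473), extracellular matrix genes (1 and 1, adjusted p = 0.923) and oxidative phosphorylation subunits (1 lower, adjusted p = 0.832).

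In TAp73-/- 757 genes were called at 4 h (340 higher, 417 lower) and 2268 at 8 h (1154 and 1114), with 77 and 192 at a change of at least 1. The probe score was -0.0502 and -0.0954 untreated, -0.354 and -0.341 at 4 h and -0.223 and -0.0749 at 8 h. With it as a covariate 98 genes were called at 4 h and 2232 at 8 h, of which 92 and 1992 were also called without it. Of the 56 and 78 called genes named by the rule 30 and 6 lost the call, Ifit3 at 4 h among them (-0.89, adjusted p = 0.0819). At 4 h the number of called genes fell when either untreated array, the second array at 4 h or either TAp73+/+ array at 4 h was left out. A TAp73+/+ array enters this contrast through the shared spread only. At 8 h leaving out the first or second untreated array gave 1069 or 1394, and the first or second array at 8 h 1209 or 1161. Fitted on the 4 arrays compared, the 4 h contrast called 294.

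**Figure D2:**
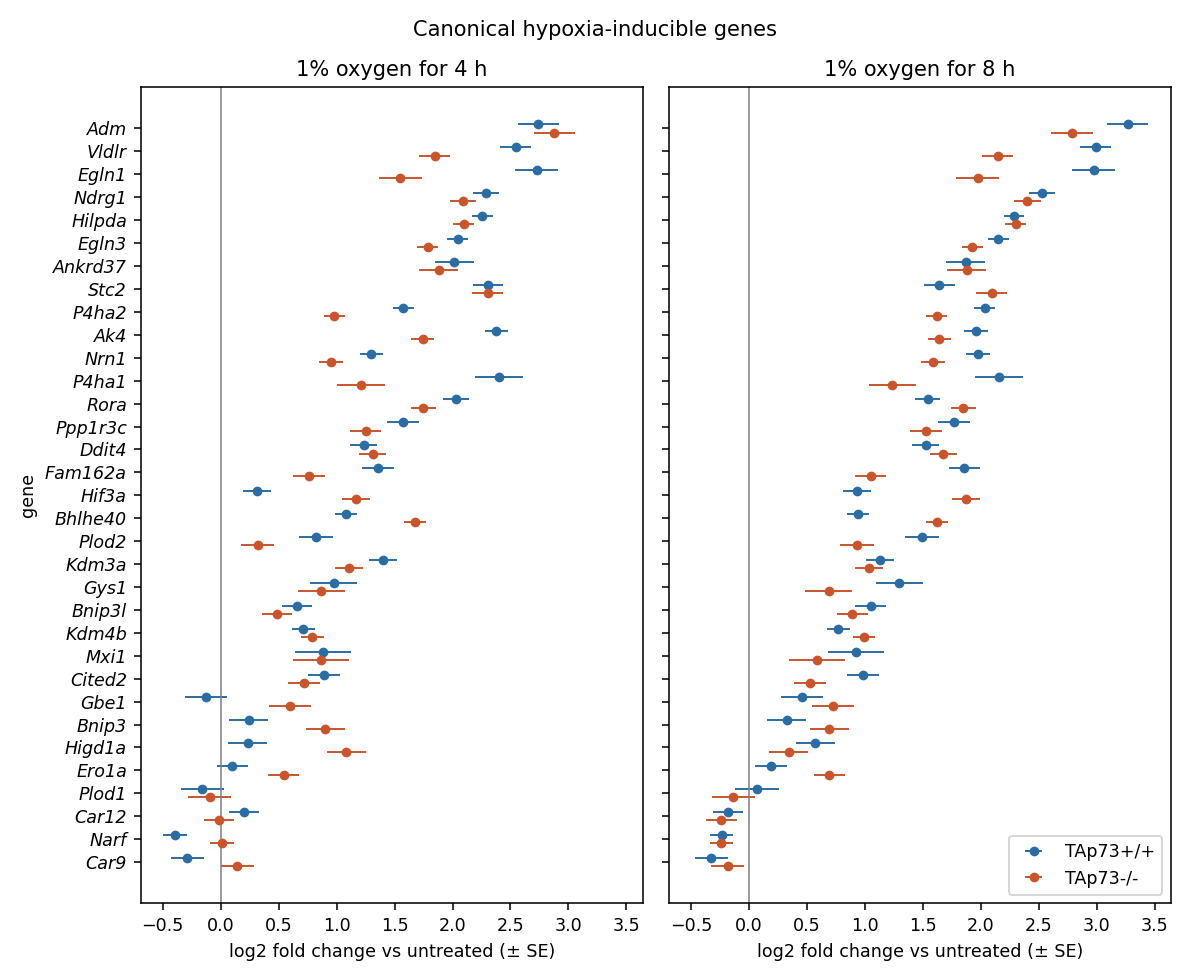
Each point is the log2 fold change (± SE) of a canonical hypoxia-inducible gene (vertical axis) against untreated cells of the same genotype at 4 h (left) and 8 h (right) of 1% oxygen, from 2 arrays per group. At 8 h 26 genes were higher in TAp73+/+ and 27 in TAp73-/-, with medians of 1.49 and 1.24.

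The fall in histone transcripts was looked at across the clustered, replication-dependent genes, a set of 47 measured genes chosen after the values were seen. In TAp73+/+ 23 were lower at 4 h (median -0.41) and 41 at 8 h (median -1.12). In TAp73-/- 15 were lower at 4 h (median -0.32) and 40 at 8 h (median -0.92), and none was higher in any of these comparisons. The 8 h medians in TAp73+/+ and TAp73-/- were -2.71 and -2.07 for the 2 H1 genes, -2.19 and -1.38 for 15 H2A genes, -1.62 and -1.22 for 9 H2B genes, -0.55 and -0.60 for 9 H3 genes, and -0.80 and -0.65 for 12 H4 genes. With the probe score as a covariate the medians over all 47 were -1.22 and -0.60 at 4 h and -1.66 and -0.95 at 8 h in TAp73+/+ and TAp73-/-. Genes called lower then numbered 6 and 12 at 4 h and 34 and 39 at 8 h. Copies within a family are nearly identical, so single members are uncertain.

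**Figure D3:**
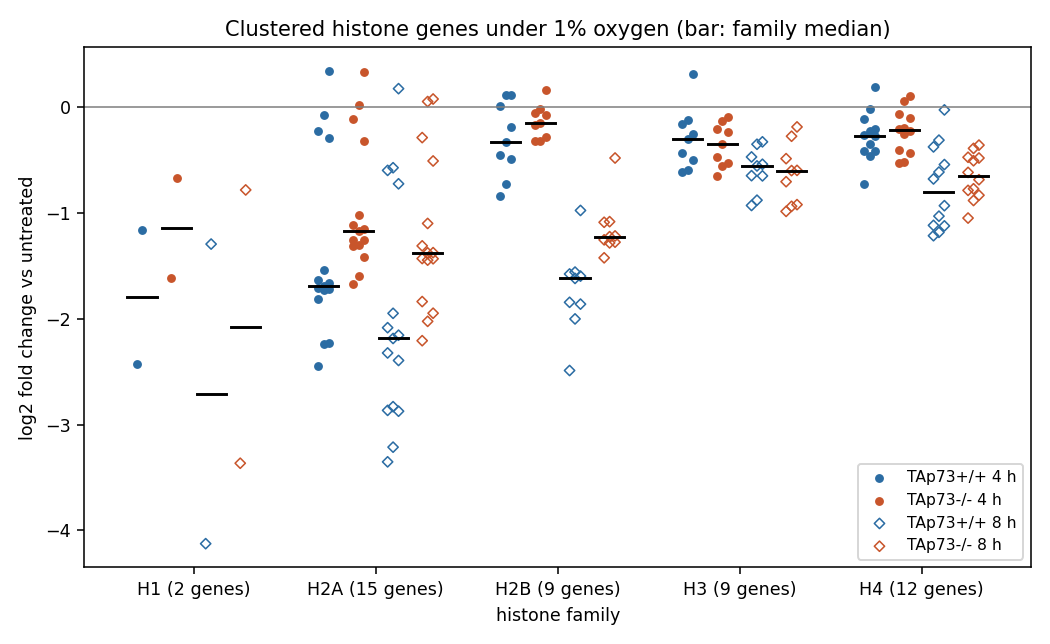
The log2 fold change against untreated cells (vertical axis) is shown for each clustered histone gene by family, with filled points for 4 h, open points for 8 h, and a bar at the family median. At 8 h the H2A medians were -2.19 in TAp73+/+ and -1.38 in TAp73-/-.

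The responses of the genotypes, which share no arrays, were set against each other across genes. Genes are not independent replicates, so the correlations describe these arrays only. At 4 h the log2 changes correlated at r = 0.632 (Spearman 0.547) and at 8 h at r = 0.694 (Spearman 0.625). Among genes called in both genotypes at 4 h, 258 were higher and 274 lower in both, where independent lists would share 40.8 and 66.7, and 9 were opposite. At 8 h the numbers were 626 and 603, with 134 and 137 from independent lists, and 8 opposite. The probe score also moved the same way in both genotypes, by -0.658 in TAp73+/+ and -0.275 in TAp73-/- at 4 h and by -0.309 and -0.0762 at 8 h, and the correlations and overlaps include whatever part follows it.

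The comparison of genotypes asks what differs between cells labelled TAp73-/- and TAp73+/+ before and during hypoxia. The largest difference was in genes induced by interferon. Untreated, Ifit3 was higher in TAp73-/- by 7.98 ± 0.13 (adjusted p = 4.11e-11), Oasl2 by 7.21, Rsad2 by 7.10, the chemokine gene Cxcl10 by 6.57 and Gbp3 by 6.001. Lgals3bp was at least 113-fold and Trim30a at least 49.0-fold higher. Ifit3 lay between 5.60 and 6.18 (log2 signal) on the 6 TAp73+/+ arrays and between 12.86 and 14.10 on the 6 TAp73-/- arrays. The growth factor gene Mdk was lower in TAp73-/- (-4.16 ± 0.10, adjusted p = 1.66e-10), the cell cycle inhibitor Cdkn1c at -3.54, Thsd4 at -3.15, Cd80 at -2.89, the guidance receptor Epha3 at -2.78, Pdgfb at -2.55 and the endothelial coreceptor Eng at -1.90.

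All 25 measured interferon-stimulated genes were higher in TAp73-/- untreated, at 4 h and at 8 h, and all 25 adjusted over the list alone. The list medians were 3.27, 3.11 and 3.24, with adjusted p = 4.35e-33, 7.43e-32 and 3.75e-32, and adjusted p = 0.000533, 0.000596 and 0.00058 with an estimated correlation. With the probe score as a covariate 24, 25 and 25 stayed called. Ccl5 was higher by 3.71, 3.70 and 3.87 at the 3 times, Ccl2 by 2.10, 2.39 and 1.48, and B2m by 1.45 untreated. With the covariate the untreated calls ended for Ccl2 (1.01, adjusted p = 0.118) and B2m (1.18, adjusted p = 0.0624). Cd14 was the called member of the 3 measured macrophage and blood markers, higher by 0.26 over the 3 times (adjusted p = 0.011), and by 0.04 with the covariate. Among inflammatory genes 9 of 17 were higher and 1 lower untreated, and the same adjusted over the list alone (median 0.50, adjusted p = 0.000525). At 4 h 9 were higher (adjusted p = 0.00276, and adjusted p = 0.063 with an estimated correlation), and at 8 h 7 were higher and 2 lower (adjusted p = 0.0125, and adjusted p = 0.0934 with an estimated correlation). The prostaglandin synthase gene Ptgs2 was at least 3.03-fold higher untreated.

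**Figure D4:**
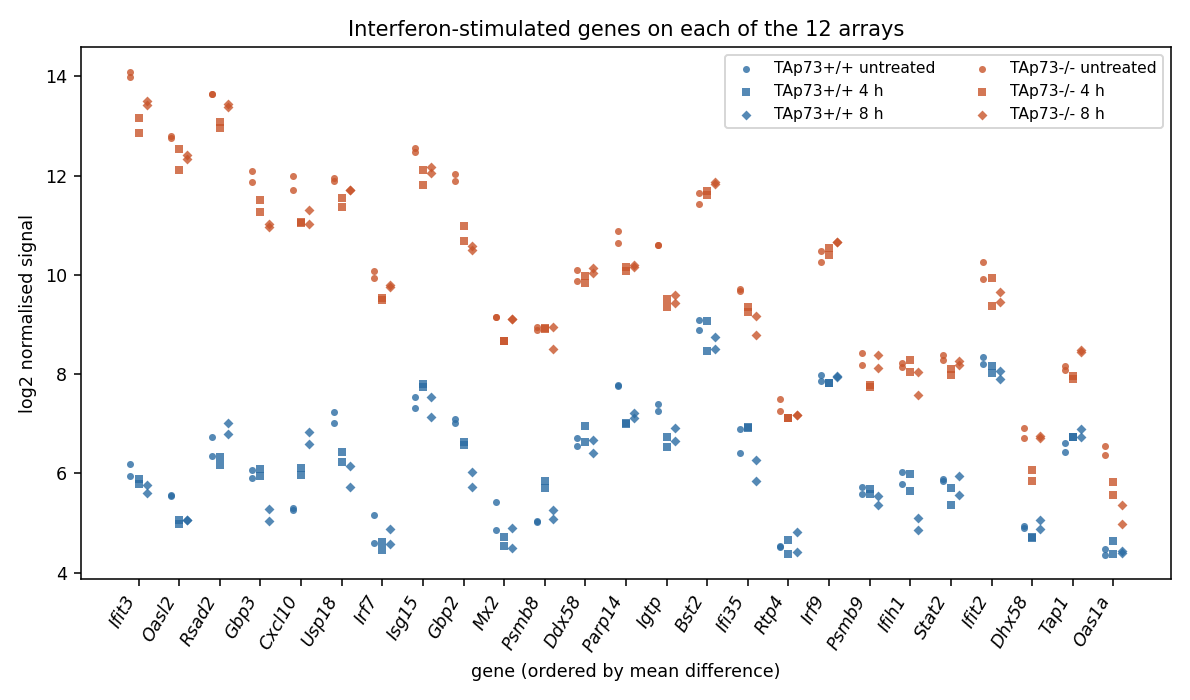
The log2 normalised signal (vertical axis) of interferon-stimulated genes, ordered by their mean difference, is shown for each of the 12 arrays, with colours for genotype and symbols for untreated, 4 h and 8 h. Ifit3 lay between 5.60 and 6.18 on TAp73+/+ arrays and between 12.86 and 14.10 on TAp73-/- arrays.

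Genes of the unfolded protein and amino acid stress response were higher in untreated TAp73-/- cells, with 18 of 25 higher and 1 lower, and the same adjusted over the list alone (median 0.71, adjusted p = 3.73e-09). The amino acid stress gene Chac1 was higher by 2.96, Trib3 by 2.40, the chaperone Hspa5 by 2.39 and Ddit3 by 1.94 (1.46 with the covariate, adjusted p = 0.057). At 8 h 17 were higher and none lower (median 0.71, adjusted p = 9.27e-08), with Hspa5 at 2.82, Ddit3 at 2.54, Herpud1 at 1.76 and Xbp1 at 1.72. At 4 h 15 were higher and 1 lower (median 0.40, adjusted p = 0.000414, and adjusted p = 0.063 with an estimated correlation), with Hspa5 at 2.27, Xbp1 at 1.63 and Chac1 at 1.32. Hypoxia-inducible genes had 16 higher and 5 lower untreated (median 0.38, adjusted p = 0.00912, and adjusted p = 0.137 with an estimated correlation), with Adm at 1.35, P4ha1 at 1.21 (-0.25 by its other probe) and Stc2 at 1.04. With the covariate P4ha1 turned to -0.18, and Adm lost its call (1.34, adjusted p = 0.215). Glycolysis genes had 7 higher and 1 lower untreated (median 0.22, adjusted p = 0.0064, and adjusted p = 0.0817 with an estimated correlation). Neither list was called at 4 h (13 higher and 5 lower, adjusted p = 0.14, for the hypoxia-inducible genes, and 4 higher and 3 lower for glycolysis) or at 8 h (10 and 5, adjusted p = 0.334, and 4 and 2). Vegfa did not differ in a called way untreated (0.13, adjusted p = 0.28), at 4 h (-0.03, adjusted p = 0.787) or at 8 h (-0.24, adjusted p = 0.0537). Its other probe past the filter read lower in TAp73-/-, most at 4 h (9.697 in TAp73+/+ and 9.153 in TAp73-/-, log2 signal). Untreated that probe read 7.723 and 7.627, and at 8 h 9.611 and 9.405.

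Other groups of genes split between the genotypes. Averaged over the 3 times, p53-family targets had 8 of 25 higher and 10 lower (adjusted p = 0.878), and untreated Bbc3 was at -0.73 and Mdm2 at -0.54 (lower by 2 of 3 probes), with both calls lost under the covariate (-0.54 and -0.32). Angiogenic factors had 9 of 29 higher and 8 lower (adjusted p = 0.915), with Pdgfb at -2.28, Eng at -1.78 and the chemokine Cxcl12 at -1.77 lower and Angptl4 at 0.81 higher. The adrenomedullin coreceptor Ramp2, of the endothelial list, was higher by 1.43. S phase and mitosis genes had 15 of 31 higher and 9 lower (adjusted p = 0.323), oxidative phosphorylation subunits 7 of 35 higher and 9 lower (adjusted p = 0.678, and with the covariate called lower with a median of -0.29, adjusted p = 0.00324), sterol synthesis genes 8 of 17 higher and 5 lower (adjusted p = 0.323), and immediate early genes 7 of 18 higher and 9 lower (adjusted p = 0.709), with Egr3 at -1.59, Egr2 at -1.34 and Fosb at -1.13 (-0.84 with the covariate, adjusted p = 0.0639). Extracellular matrix genes had 6 of 15 higher and 6 lower (adjusted p = 0.658). The gelatinase gene Mmp2 was higher by 2.99, and Loxl1 at -1.61, Col4a2 at -0.88 and Col4a1 at -0.85 were lower. Untreated, Thbs2 was at least 1.75-fold lower in TAp73-/-, where it was not detected, a call that ended with the covariate (adjusted p = 0.098) as the SE rose from 0.14 to 0.37. With the covariate the calls ended for Col4a2 (-0.45, adjusted p = 0.176) and Col4a1 (-0.60, adjusted p = 0.0631).

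Hox positional genes, which record the body region a fibroblast came from, had 10 of 22 higher and 7 lower over the 3 times (10 and 8 adjusted over the list alone, median 0.10, adjusted p = 0.443). Hoxb6 was higher by 1.68, and untreated Hoxa2 by 1.62, Hoxb9 by 1.49 and Hoxa5 by 1.32, while Hoxc6 at -1.24, Hoxc10 at -1.09 (-0.55 with the covariate, adjusted p = 0.373) and Hoxc9 at -0.90 were lower. The 3 Y-linked genes measured, Eif2s3y, Kdm5d and Uty, were each detected on both arrays of every group. Eif2s3y was higher in TAp73-/- by 0.96 untreated (0.82 ± 0.34 with the covariate, not called, adjusted p = 0.257), 1.73 at 4 h and 1.52 at 8 h. Its other probe differed by -0.065 untreated but lay near background, detected on 1 of 2 untreated arrays of each genotype. Kdm5d was higher by 0.89 ± 0.26 at 4 h, and with the covariate by 0.91 ± 0.36, no longer called because the SE grew (adjusted p = 0.0975). It was not called untreated (0.23) or at 8 h (0.30). Uty was not called untreated (0.085), at 4 h (-0.13) or at 8 h (0.17). Eif2s3y fell by 0.61 at 4 h (adjusted p = 0.005) and fell by 0.41 at 8 h (adjusted p = 0.0362) in TAp73+/+, and with the covariate these were -0.77 ± 0.38 and -0.48 ± 0.21, neither of them called (adjusted p = 0.536 and 0.187). Xist was below detection on all arrays.

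Markers of other cells were measured as well. Of 8 epithelial markers 5 were higher and none lower untreated (median 0.49, adjusted p = 0.00912, and adjusted p = 0.0817 with an estimated correlation), 6 at 4 h (adjusted p = 0.0315, and adjusted p = 0.138 with an estimated correlation) and 5 at 8 h (adjusted p = 0.0324, and adjusted p = 0.14 with an estimated correlation), with Krt8 at 1.004, Krt19 at 0.74 and Krt18 at 0.63 untreated. With the covariate these untreated values were 0.48, 0.14 and 0.81, and none was called. In the hypoxia comparisons of TAp73+/+ this list had 2 higher and 2 lower at 4 h and 4 and 1 at 8 h, and of TAp73-/- 2 and 0 at each time, with Krt19 the largest. Averaged over the times, 2 of 5 endothelial markers were higher and 1 lower (adjusted p = 0.655), 2 of 5 skeletal muscle markers were higher, with Cdh15 at 2.04 (adjusted p = 0.241), 3 of 3 neural markers were higher, with Gap43 at 1.86, 2 of 4 cartilage and bone markers were lower, and 1 of 2 adipocyte markers was lower. With the covariate neural Map2 and Nes were not called over the times (adjusted p = 0.0728 and 0.101), while Gap43 was (adjusted p = 0.0025). Neither were cartilage and bone Col2a1 and Sox9 called then (adjusted p = 0.409 and 0.814). Under hypoxia 1 adipocyte marker, Pparg (by 1 of 2 probes at 8 h in TAp73+/+), and 1 cartilage marker, Sox9, were higher in each of the 4 comparisons. Neural markers had 1 lower at 4 h in TAp73+/+ and at 8 h in TAp73-/-. Skeletal muscle markers had none called at 4 h in TAp73-/- (median -0.33, adjusted p = 0.0413, and adjusted p = 0.144 with an estimated correlation), and 3 were lower at 8 h in TAp73+/+ (adjusted p = 0.105). Endothelial markers had 3 lower at 4 h in TAp73+/+. At 8 h in TAp73-/- the muscle markers Cdh15 (-0.52) and Mylpf (-0.54) and the endothelial marker Ramp2 (-0.44) were lower too. With the covariate all of these were called lower (adjusted p = 0.0166, 0.016 and 0.0139). Of 10 housekeeping genes 1 was higher and 2 lower between genotypes over the 3 times (median -0.08, adjusted p = 0.709), and at 8 h in TAp73+/+ 2 were higher and 1 lower. The median, mean and test of a list differed in sign only in lists that were not called in the contrast concerned.

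Between the genotypes 4175 genes were called untreated (1961 higher in TAp73-/- and 2214 lower), 3973 at 4 h (2011 and 1962), 3951 at 8 h (1975 and 1976) and 6497 averaged over the 3 times (3080 and 3417). Of these 687, 567, 578 and 508 differed by at least 1, with 431 higher and 256 lower untreated, 421 and 146 at 4 h, 380 and 198 at 8 h, and 350 and 158 over the 3 times. At all 3 times 1042 genes were higher and 982 lower, where independent lists would share 65.9 and 72.6, and 49 were called in opposite directions at a pair of times. The log2 differences correlated across genes at r = 0.838 between untreated and 4 h, 0.864 between untreated and 8 h and 0.877 between 4 and 8 h. Second probes of called genes had the same sign in 78.5%, 82.2% and 83.3% of cases. With the probe score as a covariate 349, 2573, 1149 and 1096 genes were called untreated, at 4 h, at 8 h and over the 3 times, of which 319, 2261, 1022 and 1006 were also called without it. Of the 115, 113, 111 and 130 called genes named by the rule, 69, 27, 46 and 64 lost the call and 6, 0, 3 and 5 turned sign. Without the first or second TAp73+/+ array at 4 h 2229 or 2449 were called at 4 h. At 8 h 2571 or 2480 were called without the first or second TAp73+/+ array of that time and 2492 without the first TAp73-/- array.

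The last comparison asks whether the response to hypoxia itself depends on the genotype, tested as an interaction. At 4 h several stress genes rose in TAp73+/+, while in TAp73-/- Trib3 rose less, Chac1 was not called and the heat shock genes Hspa1a and Hspa1b fell. The difference was -2.66 ± 0.19 for Hspa1a (adjusted p = 0.000361), which changed by 2.04 in TAp73+/+ and by -0.62 in TAp73-/- (adjusted p = 0.0237), and -2.01 for Hspa1b, with 1.23 and -0.78 (adjusted p = 0.0245). It was -1.69 ± 0.16 for Trib3 (adjusted p = 0.00279), with 2.28 and 0.59, and -1.64 for Chac1 (adjusted p = 0.00889), with 1.54 and -0.11. Adm2 was detected in TAp73+/+ at 4 h and in none of the other 3 groups compared (adjusted p = 0.0267), so the size of its difference is not measured. Cxcl10 changed by 0.75 and -0.80, a difference of -1.56. Txnip fell by 1.76 in TAp73+/+ and fell by 2.996 in TAp73-/-, a difference of -1.23. In the other direction D930048N14Rik had a difference of 1.01, with -0.48 and 0.53. Among the groups compared, Unc13a and Galr2 were detected only in TAp73-/- at 4 h (adjusted p = 0.0267 each). Ttll3 (adjusted p = 0.0396) was not detected in TAp73-/- at 4 h. At 4 h the list of stress response genes had a median difference of -0.34 (2 genes lower and none higher, 10 lower adjusted over the list alone, adjusted p = 2.23e-06, and adjusted p = 0.0407 with an estimated correlation), and interferon-stimulated genes one of -0.33 (1 lower, 11 adjusted over the list alone, adjusted p = 1.38e-05, and adjusted p = 0.0407 with an estimated correlation). Several of the latter lie near the floor in TAp73+/+, where a fall cannot be seen. The medians of -0.21 for glycolysis (no gene called, adjusted p = 0.00328) and -0.24 for immediate early genes (no gene called, adjusted p = 0.0133) lost their calls at adjusted p = 0.0987 and adjusted p = 0.233 with an estimated correlation.

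At 8 h responses less positive in TAp73-/- included Cxcl10 (-2.11 ± 0.19, adjusted p = 0.00276), which rose by 1.42 in TAp73+/+ and changed by -0.69 in TAp73-/-, Ifi47, which was not detected in TAp73+/+ and fell by 1.67 in TAp73-/-, and Atf3 at -1.46 (adjusted p = 0.00451), with rises of 2.03 and 0.57. The lactate exporter Slc16a3 rose by 2.80 and 1.36, a difference of -1.44. Among early response genes Fosb differed by -1.18, Dusp1 by -0.94, and the matricellular genes Ccn1 by -1 and Ccn2 by -0.82. Untreated, Atf3 and Dusp1 were already higher in TAp73-/- by 1.89 and 1.48, while Fosb was at -0.665. Lims2 (adjusted p = 0.0044), Unc13a (adjusted p = 0.00276), Galr2 (adjusted p = 0.00425) and Lox (adjusted p = 0.0395) were detected in TAp73-/- at 8 h and in none of the other 3 groups compared, so the sizes of their differences are not measured. Espn and Hif3a responded more positively in TAp73-/- by 1.43 and 0.94, with 1 of the 3 Espn probes at -0.20. The histone genes H2ac22, H2ac11 and H2ac7 fell less in TAp73-/-, with differences of 1.44, 1.19 and 1.02. The list medians were -0.34 for glycolysis (1 lower, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.000195, and adjusted p = 0.0604 with an estimated correlation) and -0.28 for immediate early genes (3 lower, 7 adjusted over the list alone, adjusted p = 1.11e-05, and adjusted p = 0.0604 with an estimated correlation). Canonical hypoxia-inducible genes were not called as a list at 4 h (median -0.16, adjusted p = 0.225) or 8 h (median -0.16, adjusted p = 0.13). Vegfa was not called at either time, with differences of -0.163 at 4 h and -0.372 at 8 h. Its other probe past the filter differed by -0.447 and -0.11.

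In all 33 genes were called for a difference in the 4 h response (9 more positive in TAp73-/- and 24 less) and 52 in the 8 h response (23 and 29). With the probe score as a covariate 0 were called at 4 h and 9 at 8 h, 8 of them also called without it, among them Cxcl10 (-1.91, adjusted p = 0.0301), Slc16a3 (-1.74, adjusted p = 0.0301) and Espn (1.49, adjusted p = 0.0301). The differences for Hspa1a and Trib3 at 4 h then stood at -2.36 and -1.67, with adjusted p = 0.101 and 0.18. Single arrays moved these counts widely. For the 4 h difference, the count was 2 or 5 without the first or second TAp73+/+ array at 4 h, 16 or 253 without the first or second untreated TAp73+/+ array, and 18 without either TAp73+/+ array at 8 h. It was 11 or 3 without the first or second untreated TAp73-/- array and 50 or 4 without the first or second TAp73-/- array at 4 h. For the 8 h difference, it was 24 without the second untreated TAp73+/+ array, 25 without either TAp73+/+ array at 4 h, and 11 or 15 without the first or second one at 8 h. It was 9 or 16 without the first or second untreated TAp73-/- array and 15 or 18 without the first or second one at 8 h.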

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

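The tests of the probe score were chosen after the result was seen, while the tests of a difference between genotypes in the response were planned.

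The response to 4 h of hypoxia differed between the genotypes for 33 genes by an interaction test in limma. Less positive in TAp73-/- were Hspa1a at -2.66, Hspa1b at -2.01, Trib3 at -1.69, Chac1 at -1.64, Adm2 at -1.61, Tor3a at -1.57, Tceal3 at -1.56 and Cxcl10 at -1.56. More positive were Ttll3 at 1.52, Unc13a at 1.02, D930048N14Rik at 1.01, Galr2 at 1.01, Ypel2 at 0.995, 2810029C07Rik at 0.975, Sema7a at 0.963 and Farsa at 0.958. Lists that differed, with the preset correlation, were the unfolded protein and amino acid stress response (median -0.34), interferon-stimulated genes (median -0.33), immediate early genes (median -0.24) and glycolysis (median -0.21). With an estimated correlation the last 2 lost their calls (adjusted p = 0.233 and 0.0987). Trib3, Chac1 and the interferon-stimulated genes were already higher in untreated TAp73-/- cells, so the difference in their response goes with a different starting level. Adm2, Unc13a and Galr2 were detected in 1 of the 4 groups compared, Tor3a was not detected in untreated TAp73+/+ cells, and Ttll3 was not detected in TAp73-/- at 4 h, so their values rest in part on background readings.

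At 8 h the response differed for 52 genes. Less positive in TAp73-/- were Cxcl10 at -2.11, Ifi47 at -1.56, Atf3 at -1.46, Slc16a3 at -1.44, Hspa1b at -1.39, Gad1 at -1.34, Chac1 at -1.32, Yy2 at -1.28, Oas1a at -1.28, Fosb at -1.18, Ccn1 at -1, Dusp1 at -0.94, Ccn2 at -0.82, Angptl4 at -0.81 and Timp3 at -0.76. More positive were Lims2 at 1.88, Unc13a at 1.48, H2ac22 at 1.44, Espn at 1.43, Galr2 at 1.30, H2ac11 at 1.19, 2900055J20Rik at 1.07, H2ac7 at 1.02, Lox at 1.01 and Hif3a at 0.94. Glycolysis (median -0.34) and immediate early genes (median -0.28) differed as lists with the preset correlation, and neither did with an estimated correlation (adjusted p = 0.0604 each). Cxcl10, Chac1, Atf3 and Dusp1 were already higher in untreated TAp73-/- cells, by 6.57, 2.96, 1.89 and 1.48. The difference in their response therefore goes with a different starting level. At 8 h Atf3 and Dusp1 were higher in TAp73-/- by 0.43 and 0.54. Fosb was lower in untreated TAp73-/- cells (-0.665). Ifi47 and Oas1a were not detected in TAp73+/+ cells, so a fall was measurable in TAp73-/- alone. Among the groups compared, Lims2, Unc13a, Galr2 and Lox were detected only in TAp73-/- at 8 h. Unc13a, Galr2 and Lox were also detected in TAp73-/- at 4 h. Gad1, Yy2 and 2900055J20Rik were undetected in at least 1 of the groups compared. The sizes of the differences for these genes rest in part on background readings. The other Hspa1b probe past the filter read 0.056, and 1 of 3 Espn probes read -0.20.

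Probes of 1 gene disagreed along a graded score. It was highest on the untreated TAp73+/+ arrays (0.640 and 0.384) and lowest on those of TAp73-/- at 4 h (-0.354 and -0.341). With the score of this disagreement as a covariate 0 of these 33 differences and 8 of these 52 were still called, as the median SE rose from 0.179 to 0.256 at 4 h and to 0.204 at 8 h. If the disagreement came only from transcript forms that are the same in both replicates of a group, its 2 arrays would not differ along the same probes. Yet in 5 of the 6 groups the difference between the replicates correlated across probes, at an absolute r above 0.1, with a component of the other genotype. That component was taken from the group means and holds none of the same arrays. A property of the RNA or cRNA of each sample, such as its integrity, would act within groups too, and the median absolute r of 0.389 is consistent with that. Transcript forms may still add to the difference between groups. Forms that vary between replicates would give such correlations too, so they cannot be told apart from a property of the samples. RNA quality values are not among the data, so the property itself was not tested, and part of the score may follow genotype and oxygen.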

How the results depend on the processing

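The probe score as a covariate was chosen after the results were seen, as was leaving out arrays from the correlation of the responses, and the other tests were planned.

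Apart from the covariate, the named called genes kept direction and call in 15256 of 16469 comparisons with an alternative, lost the call in 1213 and reversed in 0. Gene lists kept theirs in 1120 of 1170, with 15 weaker, 15 newly called and 20 moved. That list total also leaves out the estimated correlation, which ended list calls in every contrast, as given below. The named called genes were chosen partly for large changes, and many comparisons left out an array outside the contrast, so agreement was likely beforehand. Among the alternatives that kept every array of the contrast, 10 of 16 named genes lost the call for the 4 h difference in at least 1. For the 8 h difference 16 of 25 did, and for the genotypes over the 3 times 3 of 130.

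With the probe score as a covariate the called genes at 4 and 8 h numbered 20 and 679 in TAp73+/+ and 98 at 4 h in TAp73-/-. Between genotypes they numbered 349 untreated, 2573 at 4 h, 1149 at 8 h and 1096 over the 3 times, and 0 and 9 for the differences in response. Lists called numbered 4 at 4 h in TAp73-/- and 4 for the 8 h difference. The score differs between the groups and is highest on the untreated TAp73+/+ arrays, so the standard errors grew (median 0.127 to 0.354 at 4 h in TAp73+/+). It reversed the median of the oxidative phosphorylation list at 4 h in TAp73+/+ (-0.27, called lower, adjusted p = 0.00976), in TAp73-/- (-0.018, adjusted p = 0.317) and in their difference (0.18, called higher, adjusted p = 0.00686). That list also became called at 8 h in TAp73+/+ (-0.15, adjusted p = 0.0114), between genotypes untreated (-0.40, adjusted p = 0.000357), at 4 h (-0.24, adjusted p = 0.0366), at 8 h (-0.24, adjusted p = 0.0241) and over the 3 times (-0.29, adjusted p = 0.00324), and for the 8 h difference (0.16, adjusted p = 0.0189), as did the extracellular matrix list for the 8 h difference (-0.29, adjusted p = 0.0265). Calls ended for Hox genes at 8 h in TAp73+/+ (adjusted p = 0.296), for stress response genes, Hox genes and muscle markers at 4 h in TAp73-/- (adjusted p = 0.272, 0.314 and 0.0706), for hypoxia-inducible genes untreated between genotypes (adjusted p = 0.113), for inflammatory genes at 8 h (adjusted p = 0.0515), and for epithelial markers untreated, at 8 h and over the times (adjusted p = 0.113, 0.139 and 0.0606). Genes reversed at 4 h in TAp73+/+ were Atp5pb (-0.82), Ccne2 (-0.64), Cdk1 (-0.83), Gusb (0.067), Hif1a (-0.12), Insig1 (0.30), Map2 (0.005), Mcm3 (-0.092), Ndufa4 (-0.38), Ndufs3 (-0.77), Plk2 (0.155), Ptpn14 (0.155) and Tyms (-0.42), and at 8 h Tyms (-0.002). Between genotypes untreated these were Atp5pb (-0.99), Hif1a (-0.091), Hoxc4 (0.435), Mcm3 (-0.48), Nsdhl (-0.119) and P4ha1 (-0.18), at 8 h Cyp51 (-0.037), Pfkp (-0.097) and Slc16a3 (0.025), and over the 3 times Arnt (0.276), Esam (-0.06), Hif1a (-0.295), Pfkp (-0.01) and Srebf2 (0.036). The cause of the reversals was not tested beyond this. Without the covariate Hif1a was 0.69 higher in TAp73-/- over the 3 times, while its other probe past the filter was lower. That probe read 6.09 and 5.08 (log2 signal, TAp73+/+ and TAp73-/-) at 4 h and 6.75 and 5.61 at 8 h, and was undetected untreated. Arnt was at -0.188 without the covariate, while another of its probes was higher in TAp73-/-, as at 6.25 and 6.76 untreated.

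Counting every probe raised the number tested and gave 7069 calls at 4 h and 4462 at 8 h in TAp73+/+, 8492, 6637, 7093 and 12423 between genotypes untreated, at 4 h, at 8 h and over the times, and 77 for the 4 h difference. A required log2 change of 1 left 356 and 237 in TAp73+/+, 77 and 192 in TAp73-/-, 687, 567, 578 and 508 between genotypes, and 29 for the 8 h difference. The share of higher calls then rose in the 8 contrasts of hypoxia or genotype, as from 42.9% to 71.1% at 4 h in TAp73+/+, and fell for the differences, from 9 of 33 to 4 of 24 and from 23 of 52 to 10 of 29.

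The differences in response, 33 at 4 h and 52 at 8 h, moved under further alternatives. Without background correction they were 163 and 121, with the deposited processed values 164 and 121, with an intensity trend 126 and 127, and on the arrays compared alone 11 and 15. At a detection p-value below 0.01 the 4 h difference gave 95. The 4 h contrast in TAp73-/- gave 294 on its own arrays. The cause was not tested, though fewer arrays leave fewer degrees of freedom.

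Replicate numbers do not pair the arrays, as replicate differences of the groups correlated at -0.250 to 0.125. With the number as a block the 8 h difference gave 24, and no other count of called genes moved by over 1.5 times.

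With each array left out in turn, the remaining array of its group was assumed to vary like the other groups. Calls at 4 and 8 h ranged over 1478 to 3330 and 1212 to 2940 in TAp73+/+ and over 191 to 957 and 1069 to 2599 in TAp73-/-. Between genotypes they ranged over 2874 to 4430 untreated, 2229 to 4282 at 4 h, 2480 to 4292 at 8 h and 5858 to 6569 over the times, and for the differences over 2 to 253 and 9 to 45. The correlation of responses ranged over 0.504 to 0.664 at 4 h and 0.635 to 0.702 at 8 h.

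With the estimated correlation the lists called numbered 5 at 8 h in TAp73+/+, 3 at 4 h in TAp73-/-, 3, 1, 2 and 2 between genotypes untreated, at 4 h, at 8 h and over the times, and 2 and 0 for the differences. With median scaling 7 lists were called at 8 h in TAp73+/+, and without background correction or with the deposited values 4 for the 8 h difference. Between 42.8% and 44.5% of probes were above background per array, which limits what can be said of dim genes.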

Other observations

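The tests of histone families, of interferon-stimulated genes away from Trp73 and of blood cell markers were chosen after the results were seen, as were the markers of cell identity.

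The cells of each genotype expressed mixed identity markers. Vim was at 12.15 and 12.59 (log2 signal, TAp73+/+ and TAp73-/-, n = 6 each), Twist1 at 10.10 and 9.41, Thy1 at 6.42 and 8.80 and Pdgfra at 6.13 and 7.51. Of 18 mesenchymal genes looked up, 7 were not detected by any probe on any array, namely Col1a1, Col1a2, Postn, Dcn, Lum, Tagln and Cnn1, and 7 were detected on all 12. Epithelial Krt18 was at 12.25 and 12.74, Krt19 at 10.62 and 10.97, Esrp1 at 10.23 and 10.70 and Cdh1 at 8.40 and 8.91, while Epcam, Krt5 and Krt14 were not detected. Cdkn2a was at 12.40 and 11.91 and Sox9 at 12.99 and 12.52. The interferon gene Ifnb1 was detected on 2 TAp73-/- arrays, with a mean of 5.77 in the untreated group, and on 0 TAp73+/+ arrays. Irf3, Cgas, Sting1 and Ifnar2 were detected on all arrays, and the probes for Ifna4, Ifng and Ifnar1 on none.

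Interferon-stimulated genes were higher on the arrays labelled TAp73-/- at every time. Spread between arrays alone is argued against as the source of the genotype contrast over the 3 times. Among 100 splits of the 12 arrays, 1, the real one, gave as many genes (6497, against 1788 for the highest other). These splits cannot exclude a chance difference between MEF lines. Each genotype may be a single line, and every other split mixes the genotypes. Of the 25 members, 1, Isg15, lies among the 90 tested genes flanking Trp73 on chromosome 4, and the 24 elsewhere were called higher. Effects in cis of DNA flanking Trp73 cannot account for the members on other chromosomes. On chromosome 4 lie 2 of the 25, and a cis effect of a longer flanking segment was not tested for the one beyond those neighbours. A flanking variant that acts in trans was not tested. Admixed blood cells would bring their abundant transcripts, but 1 of 14 blood cell markers on the array, Cd14 at 0.26, was detected on all TAp73-/- arrays and called higher, and 9 were detected on none. An interferon response of the line, from the loss of TAp73, from a flanking variant or from another difference between the lines such as passage or infection, may be the cause, and genotype and line cannot be told apart with the labels given.

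Among the 90 genes flanking Trp73, 63 were called between genotypes, 70.0% against 59.7% of other genes (Fisher's exact test, two-sided, p = 0.0518). The 5 with a change of at least 1 were Espn, Isg15, Klhl21, Thap3 and Tnfrsf4. For these neighbours a variant carried along with the targeted allele cannot be told apart from an effect of the genotype, because that share leaves it open.

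Clustered histone transcripts fell under hypoxia in each genotype, by a median of -1.12 in TAp73+/+ and -0.92 in TAp73-/- at 8 h. A fault in the probes of 1 family is argued against, since 5 families had medians below -0.3 at 8 h in TAp73-/-. In TAp73+/+ the probe score is argued against as the whole cause, since with it as a covariate calls at 8 h fell from 2599 to 679 while the histone median was -1.66, with 34 of 47 genes called lower. In TAp73-/- the covariate moved little at 8 h (2268 to 2232 calls, histone median -0.95), which leaves the score untested there. Fewer cells in S phase could lower these transcripts, and the 16 replication genes had a median of 0.0755 at 8 h in TAp73-/- and 0.20 in TAp73+/+, which decides nothing because transcripts of that list need not follow the number of cells in S phase within hours. Fewer cells in S phase and a lower level or changed polyadenylation of histone transcripts per cell therefore cannot be told apart here, and near-identical copies leave single genes uncertain.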
